A study of Mus musculus with 36 samples.

How the data were processed

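Whole blood of C57BL/6 mice, a common inbred laboratory strain, was profiled on 36 MEEBO arrays, which carry long oligonucleotide probes designed on mouse exons. Of these arrays 17 held blood of mice infected with Plasmodium chabaudi AS, a rodent malaria parasite, and 19 held blood of mock-infected mice, called uninfected here. Sampling times ran from 0 h to 72 h after infection at intervals of 8 h. Per the labels' protocols, RNA was extracted with a kit for mouse blood, amplified with incorporation of amino allyl groups and coupled to Cy5. The Cy3 channel of every array held the same kind of common reference, amplified universal mouse RNA to which pooled amplified sample RNA had been added. The added sample RNA raises blood transcripts in the reference, so the ratios compare arrays with one another and are not levels of expression.

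The deposited values were used as log2 ratios of Cy5 over Cy3, 1 value per probe and array, with no pooling of arrays by the authors as far as the columns show. The direction follows from the dyes in the labels. The base of the logarithm was not stated and was taken as 2 from the range of the values, so every fold and log2 size given here rests on that base. The background correction, spot filter and normalization were not given in the sources used here. The arrays were not centred on a common median: the array medians ran from -1.16 to -0.03. In hour order from 0 h to 72 h, the medians of the infected arrays were -0.20 and -0.91 at 0 h, -0.20 and -0.03 at 8 h, -0.19 and -0.05 at 16 h, -0.17 and -0.41 at 24 h, -0.38 and -0.37 at 32 h, -0.26 at 40 h, -0.20 at 48 h, -0.18 at 56 h, -0.07 and -0.14 at 64 h, and -0.35 and -0.17 at 72 h. Those of the uninfected arrays were -0.35 and -0.27 at 0 h, -0.71 and -0.56 at 8 h, -0.17 and -0.46 at 16 h, -0.48 and -0.46 at 24 h, -0.03 and -0.03 at 32 h, -0.13 and -0.68 at 40 h, -0.33 and -0.26 at 48 h, -0.24 at 56 h, -1.16 and -0.40 at 64 h, and -0.49 and -0.36 at 72 h. The standard deviation of the ratios of an array ran from 0.868 to 1.92, so the scale also differed between arrays.

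The table held 38457 probes, and 13.2% of its values were missing. Platform annotation gave 1 gene symbol for 29446 probes, several for 760 and none for 8251, and a match of 28725 gene identifiers to a current mouse gene table renamed 0 of them. Probes with a value on at least 29 of the 36 arrays were kept, which left 29247, of which 23490 had 1 symbol. Values of the probes of a gene were averaged per array, which gave 16113 genes, 4850 of them with more than 1 probe. Probes of a gene that differed in sign are named beside the gene. Members of gene families with similar sequence, such as Klra, Stfa, Gzm and Ifit genes, can bind to one another's probes, so the value of a single member is uncertain.

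Arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes). A model held 1 term for each of the 10 time points and infected minus uninfected terms for 0 h and for 8 to 72 h. Its 8 to 72 h term gave the comparison over all hours after 0 h. A model with the same time terms and separate infection terms for 0 h, for 8 to 24 h, for 32 to 48 h and for 56 to 72 h gave the comparisons by window. The windows were formed because a time point held at most 2 arrays per arm. Moderated F tests of nested models gave the difference of the infection effect between the 3 windows after 0 h, an effect at any of the 9 time points from 8 to 72 h in a model of 20 group means, and a cycle of 24 h in the 19 uninfected arrays. Residual degrees of freedom were 24, 22 and 16 in the models of all hours, of windows and of group means. P values were adjusted by the method of Benjamini and Hochberg over all genes tested, and an adjusted p below 0.05 was the threshold. Each array was treated as a separate sample. The labels do not say whether the arrays of a group came from separate mice, so the p values measure the spread between arrays, which may in part be technical. Arrays give no counts, and the number of arrays limits the precision.

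For gene groups 21 lists were fixed: NK cell markers, cytotoxic granule, type I interferon-stimulated, interferon gamma-induced, MHC class II, cytokines and chemokines, erythroid, platelet, B cell, T cell, neutrophil, monocyte, eosinophil and basophil, dendritic cell, proliferation, circadian clock, glucocorticoid response, immediate early and heat shock, heme and oxidative stress, ribosomal protein and glycolysis. Each list was tested with limma's cameraPR on the moderated t statistics of the 8 to 72 h term and of the 3 windows, with a preset correlation between genes of 0.01 and adjustment over the 84 tests. The test asks whether the members of a list rank above or below all other genes. Members past the threshold were counted with p values adjusted over all genes and, where stated, adjusted over the list alone. The tests were repeated with a correlation estimated from the residuals. A score per array, the mean over the members of a list of the value minus the gene's mean over uninfected arrays, was compared between arms in each window by a two-sided exact permutation test, with adjustment over all such tests. The assignments ran over all arrays of a window without regard to the hour, unlike the models, which hold time terms. The scores are not taken relative to other genes, so a shift of all genes between the arms moves every list score.

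Genes were named by a rule: the 10 largest rises and falls past the threshold for 8 to 72 h, the 5 largest of each for every window, the 10 smallest p values of each F test, the 3 members with the largest change of each list past its threshold, a panel of NK cell, interferon, red cell, lymphocyte, myeloid, platelet and proliferation genes, where tested, whatever their result, and the measured clock genes for the cycle. Predicted genes, cDNA clones and unnamed probes were counted but passed over for naming. The groups, models, lists, naming rule and most alternatives were fixed before the data were examined.

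The alternatives fixed in advance were centring, scaling or quantile normalization of the arrays, other filters on missing values, single probes, robust moderation, array weights, ranges of the array numbers in the titles as a block, the array number as a linear term, no time terms, each window fitted alone, other models of the cycle and other list tests, and leaving out each array in turn. After the values had been seen, arrays 241, 242, 244 and 245, arrays 195 to 199 and arrays 206, 210, 224 and 233 were also left out as sets, and centring was combined with scaling. The models were tested on simulated data with the real design, 16113 genes and noise independent between genes, of the same spread on every array. The real arrays differed in median and scale, so the shares below may not hold for them. Of 100 genes changed by 2 on the log2 scale, the share recovered was 100% for 8 to 72 h, 77% for 8 to 24 h, 58% for 32 to 48 h, 67% for 56 to 72 h, 14% for 0 h, 30% for the difference between windows and 72% for the cycle. Of 100 genes changed by 1 it was 62%, 19%, 4%, 11%, 0%, 1% and 13% in the same order. The share of calls that were false was 10% for 8 to 72 h, 4% for 8 to 24 h, 7.46% for 32 to 48 h, 6.02% for 56 to 72 h, 6.67% for 0 h, 3.12% for the difference between windows and 4.49% for the cycle, so some lay above the 5% aimed at. A change of 2 at 1 time point alone was recovered in 0% of 100 genes by the test of any time point. Tables were prepared with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.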

Results

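Blood was taken from infected and uninfected mice at 10 time points, and the ratio of blood RNA to a common reference was measured for 16113 genes. At 0, 8, 16, 24, 32, 64 and 72 h there were 2 infected arrays, and at 40, 48 and 56 h there was 1. Uninfected blood was measured on 2 arrays at each time point except 56 h, which had 1. The windows held 2 infected and 2 uninfected arrays at 0 h, 6 and 6 at 8 to 24 h, 4 and 6 at 32 to 48 h, and 5 and 5 at 56 to 72 h. Between 28170 and 37260 probes had a value on an array. The median correlation between arrays was 0.767 across probes, which are not independent replicates, and 0.817 between arrays of the same group. Over the 16 same-group pairs it ran from 0.285 to 0.920, and the lowest was that of the 2 infected 16 h arrays. The series title concerns natural killer (NK) cells, lymphocytes that kill target cells without prior sensitization, so the comparisons ask when NK cell transcripts and those of other blood cells and programs differed after infection.

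From 8 to 72 h, infected blood carried more RNA of interferon-stimulated, cytotoxic and monocyte genes than uninfected blood (15 and 17 arrays). Gzmb, a granzyme that cytotoxic lymphocytes deliver into target cells, rose by 3.34 ± 0.29 on the log2 scale (SE, adjusted p = 3.92e-09), a 10.1-fold difference, and 14 of the 15 infected arrays lay above all uninfected arrays. Cfb, factor B of the alternative complement pathway, rose by 3.53 ± 0.31, and Ifit3, an interferon-stimulated antiviral gene, by 3.19 ± 0.25 (adjusted p = 3.92e-09 and 1.44e-09). The other genes with the largest rises were the schlafen gene Slfn4 at 3.28, the interferon-induced GTPase gene Gbp2 at 3.09, the myeloid membrane gene Ms4a6d at 3.02, the DNA sensor family gene Ifi204 at 2.99, the RNA sensor gene Ifih1 at 2.79, Ifit2 at 2.72 and the mitochondrial nucleotide kinase gene Cmpk2 at 2.65. The type I interferon-stimulated list had 27 of 36 members higher, 33 when adjusted over the list alone, with a median of 1.27. In the interferon gamma-induced list 16 of 29 members rose, 26 when adjusted over the list alone, with a median of 1.05. For the cytotoxic granule list, which holds granzymes and perforin, the counts were 8 of 16 and 14, with a median of 1.12, and for the monocyte list 14 of 34 and 23, with a median of 1.09. The calls of these 4 lists held with an estimated correlation, with adjusted p values of 1.10e-09, 4.67e-06, 0.00139 and 0.00201.

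Markers of NK cells, of platelets and of neutrophils were also higher over 8 to 72 h. Of the 33 NK cell markers 11 rose, 24 when adjusted over the list alone, with a median of 0.85. Among them Klra2, a Ly49 family receptor gene, rose by 1.92 ± 0.27, Klre1 by 1.77 ± 0.39 and Ncr1, which encodes the activating receptor NKp46, by 1.66 ± 0.35. The list was past the threshold with the preset correlation and lost with an estimated one (adjusted p = 0.0518 with an estimated correlation). The platelet list had 8 of 26 members higher, 19 when adjusted over the list alone, with a median of 0.93, and Gp5, a platelet glycoprotein gene, rose by 1.69. Its call was lost as well, with an adjusted p of 0.0927 with an estimated correlation. In the neutrophil list 6 of 37 members rose, 14 when adjusted over the list alone, with a median of 0.56. Fpr2, a receptor for formylated peptides, rose by 1.81 ± 0.28. That call was lost with an adjusted p of 0.441 with an estimated correlation. The cytokine and chemokine list had 8 of 30 members higher, 12 when adjusted over the list alone, with a median of 0.39 (adjusted p = 0.0507 with an estimated correlation), led by Ccl12, a monocyte chemoattractant, at 1.64 ± 0.26, Il18 at 1.56 and Ccl4 at 1.49. The heat shock gene Hspa1b rose by 1.56 ± 0.30, and its list of immediate early and heat shock genes had 1 of 26 members higher, over all genes and over the list alone, at a median of 0.40 (adjusted p = 0.924 with an estimated correlation).

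Lymphocyte and red cell lists showed no such rise over 8 to 72 h. The B cell list ranked below the other genes with a median of -0.12 and 0 of 32 members past the threshold in limma, over all genes or over the list alone. MHC class II, the antigen presentation molecules of B cells, dendritic cells and macrophages, had a list median of -0.36 with 1 of 10 members higher and 0 lower. Cd79a, a signalling chain of the B cell receptor, was at -0.37 ± 0.31 (adjusted p = 0.897). The erythroid list had a median of -0.02 with 1 of 38 members higher, or 2 higher and 1 lower when adjusted over the list alone. Car1, a carbonic anhydrase of red cells, was at -0.62 ± 0.17 (adjusted p = 0.0527). These 3 list calls were lost with an estimated correlation, with adjusted p values of 0.924, 0.918 and 0.924. Lists not past the threshold were T cell with a median of 0.11, dendritic cell at 0.14, eosinophil and basophil at 0.19, proliferation at 0.24, ribosomal protein at 0.22, circadian clock at 0.09, glucocorticoid response at 0.02, heme and oxidative stress at 0.26 and glycolysis at 0.15. The tests of the T cell and glucocorticoid lists pointed below the other genes although their medians were above 0. Of the panel, the T cell genes Cd3e and Cd8a were at 0.11 ± 0.34 and 0.06 ± 0.32, the proliferation marker Mki67 at 0.33 ± 0.28 and Ifng, which encodes interferon gamma, at 0.11 ± 0.20, with adjusted p values of 0.966, 0.985, 0.897 and 0.943.

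Over 8 to 72 h limma called 261 genes higher and 0 lower. At an unadjusted p below 0.05 there were 1097 higher and 112 lower genes, where 806 in all are expected by chance. The median difference of all genes was 0.12, and relative to it the type I interferon-stimulated list stood at 1.16, the NK cell markers at 0.73 and the B cell list at -0.24. With the ranges of array numbers as a block 431 genes were called, with the array number as a linear term 479, and with array weights 985.

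**Figure D1:**
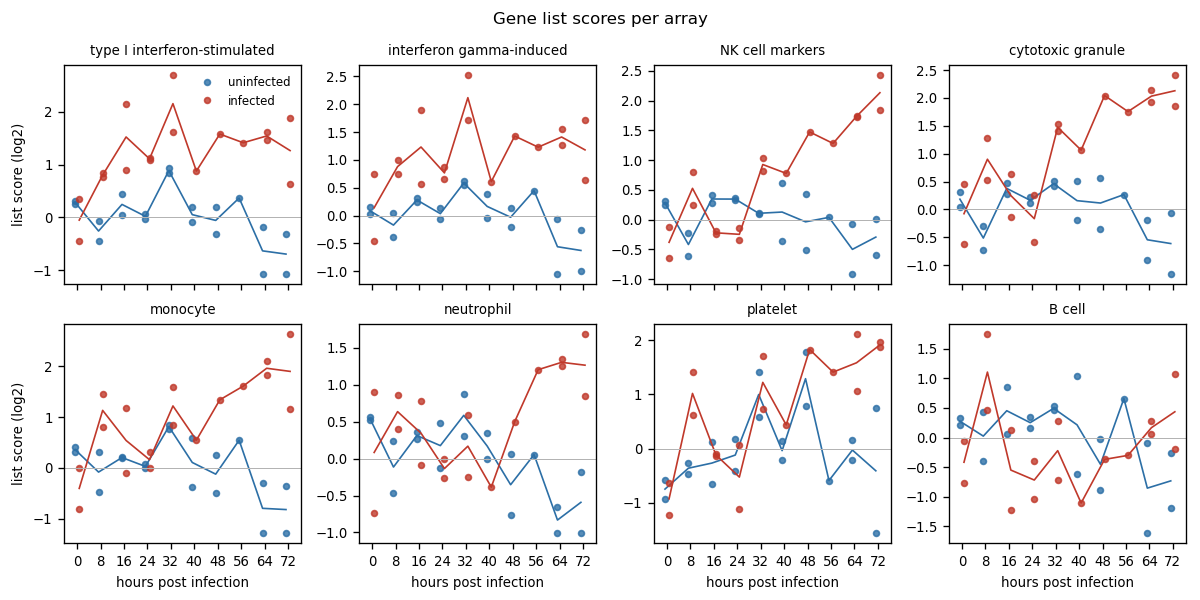
Score of 8 gene lists on each array (mean log2 ratio of the members minus their mean over uninfected arrays) against hours post infection, with red points for infected and blue points for uninfected arrays and lines through the means at each hour. At 72 h the mean NK cell marker score was 2.13 in infected and -0.29 in uninfected blood, while at 24 h the means were -0.25 and 0.34.

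Interferon-stimulated genes were already higher at 8 to 24 h, when NK cell markers were not (6 and 6 arrays). Cxcl10, a chemokine induced by interferons that attracts T cells and NK cells, rose by 3.89 ± 0.56 (adjusted p = 0.000725), a 14.9-fold difference, with all 6 infected arrays above all uninfected arrays. Its difference was 0.70 at 8 h, 5.61 at 16 h and 5.36 at 24 h, and then 3.38 at 32 h and 1.07 at 40 h. Slfn5 rose by 3.18 ± 0.49, Slfn4 by 3.01 ± 0.44, Cfb by 2.92 ± 0.49 and Ifit2 by 2.86 ± 0.44, with adjusted p values of 0.00106, 0.000725, 0.00269 and 0.00106. In the type I interferon-stimulated list 9 of 36 members rose, 25 when adjusted over the list alone, with a median of 1.03, and in the interferon gamma-induced list 4 of 29, 12 when adjusted over the list alone, with a median of 0.80. Both calls held with an estimated correlation, with adjusted p values of 0.00139 and 0.0357, and in exact permutation tests of the array scores both lists were higher in infected blood at an adjusted p of 0.0357. Infected 16 h replicate 2, an array with a narrow range of ratios, stood apart in both lists, with scores of 2.15 and 1.89 where the nearest infected arrays had 1.13 and 1.01. Without it the medians of the list type I interferon-stimulated, 8 to 24 h, and the list interferon gamma-induced, 8 to 24 h, were 0.889 and 0.570, and both calls held with the preset correlation. The raw exact p of 0.00216 is the smallest that 924 assignments allow.

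Of cell type genes at 8 to 24 h, Gzmb rose by 1.74 ± 0.30 (adjusted p = 0.00301), the monocyte genes Ms4a6d by 2.48 ± 0.42 and Ms4a4c by 1.84 ± 0.36, and Ccl12 by 2.32 ± 0.38. In the NK cell marker list 0 of 33 members were past the threshold in limma, over all genes or over the list alone, and the median was -0.08. Ncr1 was at 0.06 ± 0.37, Klrd1, the CD94 receptor chain, at -0.93 ± 0.45 and Klrb1c, the NK1.1 antigen, at -0.49 ± 0.33, with adjusted p values of 0.999, 0.699 and 0.795. The list score was 0.94 higher in infected blood at 8 h, and its difference was -0.57 at 16 h and -0.59 at 24 h. At 8 h the scores of all 21 lists were higher in infected blood, from 0.41 for the erythroid to 1.41 for the cytotoxic granule list, with 1.08 for the B cell list. The type I interferon-stimulated list at 1.06 and the interferon gamma-induced list at 1.05 did not stand out at that hour. At 16 h and 24 h the differences were 1.28 and 1.09 for the type I list and 0.95 and 0.73 for the interferon gamma list. At 8 h, infected replicate 1 had the highest value of Alb, the gene of serum albumin. Without that array the NK cell marker median was -0.28. The list then ranked below the other genes past the threshold with the preset correlation, as it did at -0.27 without uninfected 8 h replicate 1. With all arrays and an estimated correlation the adjusted p of the NK cell list was 0.961. Members higher were 1 of 16 in the cytotoxic granule list, 2 of 34 in the monocyte list, 0 of 26 in the platelet list and 1 of 30 in the cytokine and chemokine list, and 1, 6, 0 and 4 when adjusted over the list alone, with medians of 0.19, 0.41, 0.46 and 0.32. All these lists ranked above the other genes with the preset correlation, and their adjusted p values with an estimated correlation were 0.918, 0.505, 0.924 and 0.387. The B cell, MHC class II and erythroid lists ranked below the other genes with medians of -0.30, -0.54 and -0.15 and 0 members past the threshold, over all genes or over the list alone. Their adjusted p values with an estimated correlation were 0.918, 0.707 and 0.918, and the erythroid median turned to 0.16 after scaling of the arrays. Named members of these lists were H2-Ob at -0.96, H2-Aa at -0.96, Vpreb3 at -0.84 and Alas2, the heme synthesis enzyme of red cells, at -0.91, none past the threshold.

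At 8 to 24 h limma called 27 genes higher and 0 lower. At an unadjusted p below 0.05 there were 702 higher and 443 lower, where 806 in all are expected by chance. After scaling of the arrays to a common spread 0 genes passed, with 790 at an unadjusted p below 0.05, and Cxcl10 did not pass. The largest adjusted p of Cxcl10 over the alternatives was 0.133. Fitted on the 12 arrays of this window alone 13 genes passed, without time terms 44, and without arrays 195 to 199 only 6.

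At 32 to 48 h cytotoxic and interferon-stimulated genes were higher, and NK cell markers stood above the other genes as a list (4 and 6 arrays). Gzmb rose by 4.11 ± 0.34 (adjusted p = 1.40e-08), a 17.2-fold difference with all 4 infected arrays above all uninfected arrays, and Gzma, another granzyme, by 2.45 ± 0.43 (adjusted p = 0.00361). Cfb rose by 3.93 ± 0.55, Gbp2 by 3.71 ± 0.46, Cmpk2 by 3.42 ± 0.46 and Tgtp1, an interferon gamma-induced GTPase, by 3.30 ± 0.35, with adjusted p values of 0.000185, 3.25e-05, 0.000101 and 2.11e-06. Klre1 rose by 2.16 ± 0.44 (adjusted p = 0.0176), and Ncr1 at 1.70 ± 0.42, Klrk1, which encodes NKG2D, at 1.61 ± 0.37 and the perforin gene Prf1 at 1.51 ± 0.51 did not pass, with adjusted p values of 0.109, 0.0684 and 0.697. Xcl1, a chemokine of NK and CD8 T cells, rose by 1.80 ± 0.30. The NK cell marker list had 2 of 33 members higher, 16 when adjusted over the list alone, with a median of 0.88 (adjusted p = 0.00474 with an estimated correlation), and its score was higher in an exact permutation test (adjusted p = 0.0375). The cytotoxic granule list had 2 of 16, 8 when adjusted over the list alone, with a median of 1.03 (adjusted p = 0.000109 with an estimated correlation).

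The type I interferon-stimulated and interferon gamma-induced lists at 32 to 48 h had medians of 1.03 and 1.11 with 9 of 36 and 5 of 29 members higher, 20 and 15 when adjusted over the list alone. Both calls held with an estimated correlation, with adjusted p values of 1.77e-05 and 0.000109. In the exact permutation test of scores the type I list missed the threshold at an adjusted p of 0.0526. The monocyte list had 6 of 34 members higher, 12 when adjusted over the list alone, among them Ms4a6d at 3.06, Ly6c1 at 2.47 and the Fc receptor gene Fcgr1 at 2.46, with a median of 0.50 (adjusted p = 0.0309 with an estimated correlation). The platelet list at a median of 0.56 and the cytokine and chemokine list at 0.11 ranked above the other genes with 0 of 26 and 1 of 30 members higher, 0 and 2 when adjusted over the list alone, and were lost with an estimated correlation (adjusted p = 0.508 and 0.301). The B cell, MHC class II, proliferation and ribosomal protein lists ranked below the other genes with medians of -0.63, -0.95, -0.45 and -0.50 and 0 members past the threshold, over all genes or over the list alone. Their adjusted p values with an estimated correlation were 0.836, 0.836, 0.961 and 0.924. Cr2 and Fcrla, 2 B cell genes, were at -1.79 ± 0.67 and -1.76 ± 0.61 without passing. The median of the neutrophil list was -0.12 and that of the T cell list -0.21, neither past the threshold.

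At 32 to 48 h limma called 38 genes higher and 0 lower, with 266 higher and 222 lower at an unadjusted p below 0.05. These are fewer in all than the 806 expected by chance. The median difference of all genes was -0.20, and relative to it the NK cell markers stood at 1.07, the B cell list at -0.44 and the proliferation list at -0.25. The median of all genes turned to 0.16 without arrays 241, 242, 244 and 245. It was 0.08 with the array number as a linear term, so these relative values depend on the processing. Both uninfected arrays at 32 h had a narrow range of ratios, and without these and 2 infected arrays of the same kind, from 8 h and 16 h, 10 genes passed and the proliferation and ribosomal medians turned to 0.54 and 0.22. The count was 12 without the infected array at 48 h, 24 without infected 32 h replicate 1, 23 without uninfected 32 h replicate 2, and 84 after centring. With array weights the direction turned, with 264 genes higher and 3023 lower.

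**Figure D2:**
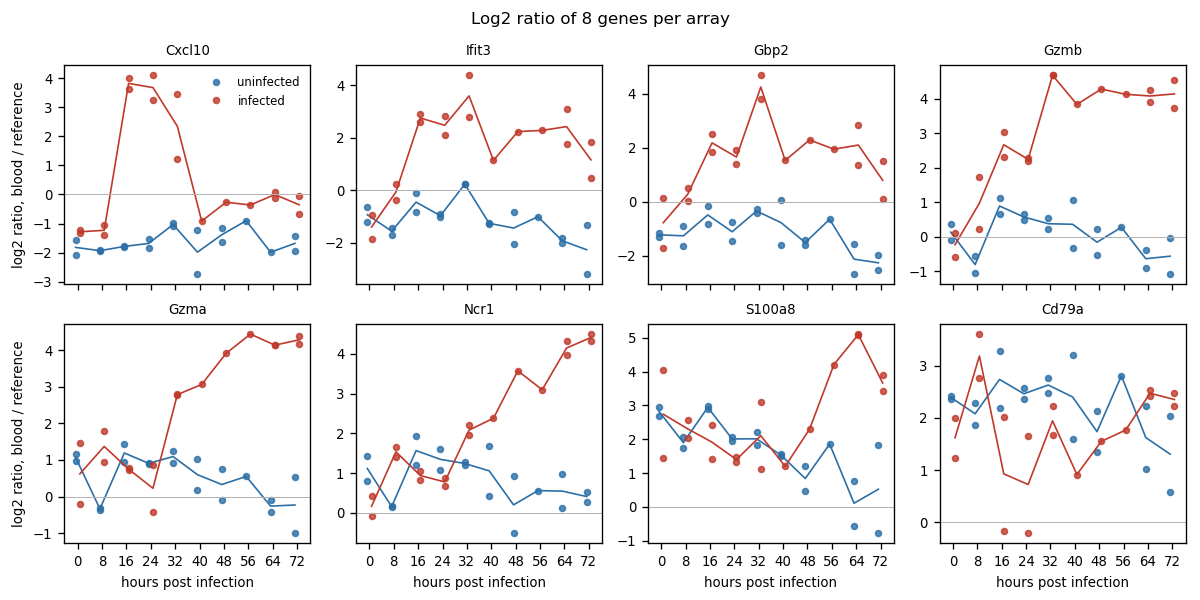
Log2 ratio of 8 genes on each array against hours post infection, with red points for infected and blue points for uninfected arrays and lines through the means at each hour. The infected minus uninfected difference of Cxcl10 was 5.61 at 16 h and 1.33 at 72 h, while that of Ncr1 was -0.63 at 16 h and 3.60 at 64 h.

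At 56 to 72 h NK cell, cytotoxic, monocyte, neutrophil and platelet genes were higher in infected blood (5 and 5 arrays). Gzmb rose by 4.54 ± 0.33 (adjusted p = 5.07e-10), a 23.3-fold difference. Gzma rose by 4.34 ± 0.42 and Klra16, a Ly49 family gene of NK cells, by 4.55 ± 0.49, with adjusted p values of 1.54e-07 and 4.04e-07. For each of them all 5 infected arrays lay above all uninfected arrays. Transcripts of other Klra genes can bind to Klra16 probes, so the rise may be theirs. Ncr1 rose by 3.54 ± 0.40, Klrd1 by 3.49 ± 0.49, Klrk1 by 3.06 ± 0.36, Prf1 by 2.12 ± 0.49, Klrb1c by 1.46 ± 0.36 and Ccl5, a chemokine of activated lymphocytes and platelets, by 3.11 ± 0.54. The NK cell marker list had 26 of 33 members higher, 30 when adjusted over the list alone, with a median of 2.13, and the cytotoxic granule list 13 of 16 and 16 with a median of 2.17. Both held with an estimated correlation, with adjusted p values of 0.00490 and 0.00139. Il2rb at 0.98 ± 0.33, the transcription factor gene Eomes at 0.91 ± 0.40, whose 2 probes differed in sign, and Ifng at 0.55 ± 0.33 did not pass, with adjusted p values of 0.0645, 0.143 and 0.290.

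Myeloid and platelet genes rose with them at 56 to 72 h. Mpeg1, a pore-forming protein of macrophages, rose by 4.11 ± 0.59, the monocyte lectin gene Clec4a3 by 4.1 ± 0.44, and Csf1r, the receptor for macrophage colony-stimulating factor, by 1.82 ± 0.42 (adjusted p = 2.79e-05, 4.04e-07 and 0.00689). The 2 probes of Csf1r disagreed, at 0.29 and 3.34. Of the monocyte list 25 of 34 members rose, 29 when adjusted over the list alone, with a median of 2.54. In the neutrophil list 19 of 37 rose, 25 when adjusted over the list alone, with a median of 1.72. S100a8, a calcium-binding protein abundant in neutrophils, rose by 3.73 ± 0.51, the chitinase-like gene Chil3 by 4.09 ± 0.54 and the stefin gene Stfa3 by 3.76 ± 0.37. Both calls held with an estimated correlation, with adjusted p values of 0.00257 and 0.0354. The platelet list had 19 of 26 members higher, 20 when adjusted over the list alone, with a median of 2.26. Among them Tubb1, the tubulin of platelets, was at 4.07 ± 0.63, Pf4, platelet factor 4, at 3.32 ± 0.49 and F13a1 at 3.04 ± 0.53. The list call was lost with an estimated correlation (adjusted p = 0.120).

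The interferon lists stayed high at 56 to 72 h. In the type I interferon-stimulated list 25 of 36 members rose, 29 when adjusted over the list alone, with a median of 1.74 (adjusted p = 0.00571 with an estimated correlation). In the interferon gamma-induced list 18 of 29 rose, 22 when adjusted over the list alone, with a median of 1.59, lost with an estimated correlation (adjusted p = 0.0518). Irf7, a transcription factor of the interferon response, rose by 2.23 ± 0.44, whereas Cxcl10 at 1.35 ± 0.66 and Cxcl9 at 0.87 ± 0.45 did not pass (adjusted p = 0.193 and 0.218). Cytokine and chemokine genes had 8 of 30 members higher, over all genes and over the list alone, with a median of 0.72. Members with the largest rises were Ccl4 at 2.85 ± 0.36, Il18 at 2.57 ± 0.44 and Il1b at 2.52 ± 0.41. Immediate early and heat shock genes had 8 of 26, 15 when adjusted over the list alone, with a median of 1.38. These included the inducible transcription factor genes Nr4a1 at 2.70 ± 0.52 and Fos at 2.19 ± 0.70 and the phosphatase gene Dusp1 at 2.49 ± 0.59. Ribosomal protein genes had 2 of 30, 15 when adjusted over the list alone, with a median of 1.16, among them Rpl35 at 1.69 ± 0.45. The calls of these 3 lists were lost with an estimated correlation, with adjusted p values of 0.395, 0.918 and 0.918. Lists not past the threshold were B cell at 0.56, T cell at 0.56, MHC class II at 0.65, erythroid at 0.26, dendritic cell at 0.71, eosinophil and basophil at 0.96, circadian clock at 0.48, glucocorticoid response at 0.91, heme and oxidative stress at 1.03, glycolysis at 0.95 and proliferation at 0.92. The test of the erythroid list pointed below the other genes although its median was above 0. In the exact permutation test of scores, the eosinophil and basophil list and the glycolysis list did pass, each at an adjusted p of 0.0357. The ribosomal protein list, past the threshold with the preset correlation, had the same value. That test does not compare a list with other genes. The median difference of all genes was 0.43 in this window, so a shift of all genes may have entered these results. The NK cell markers had the same adjusted p in that test, at the smallest raw p that 252 assignments allow. Cd79a was at 0.55 ± 0.52, Cd3e at 0.94 ± 0.58, Cd8a at 0.24 ± 0.59 and Mki67, whose probes differed in sign, at 0.67 ± 0.49, none past the threshold.

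At 56 to 72 h limma called 1364 genes higher and 9 lower. The falls were small in number and near the threshold: Ccdc103, a gene of cilia assembly measured on 4 infected and 2 uninfected arrays, fell by 2.69 ± 0.85 (adjusted p = 0.0484), Tnn by 1.46 ± 0.44, Lrrc4c by 1.41 ± 0.43, Ubac1 by 1.26 ± 0.41 and Cdc25b, a phosphatase of the cell cycle, by 1.24 ± 0.40. The median difference of all genes in this window was 0.43, and relative to it Gzmb stood at 4.11 (4.30 at 32 to 48 h), Ncr1 at 3.11, S100a8 at 3.29 and Klrb1c at 1.02, the NK cell list at 1.70, the monocyte list at 2.11, the platelet list at 1.82, the interferon gamma-induced list at 1.16 (1.30 at 32 to 48 h), the ribosomal protein list at 0.73 and the B cell list at 0.13. At 64 h and 72 h the scores of all 21 lists were higher in infected blood, with the B cell list at 1.02 and 1.17 and the monocyte list at 2.76 and 2.72. All 21 lists also stood below their uninfected mean in uninfected blood at these hours, the monocyte list at -0.79 and -0.82 and the NK cell list at -0.50 and -0.29. At 56 h, with 1 array per arm, the differences were -0.96 for B cell and 1.24 for NK cell markers. With each array centred on its median 761 genes were higher and 82 lower, with quantile normalization 666 and 61, with centring and scaling together 588 and 60, and with array weights 4652 and 390. In all, 760 genes passed with array number ranges as a block, 668 without time terms, 862 without arrays 195 to 199, 3242 without arrays 206, 210, 224 and 233 and 2884 fitted on this window alone. The count was 2541 without either array at 56 h, 674 and 609 without infected 64 h replicate 1 or 2, 441 without infected 72 h replicate 2, 485 without uninfected 64 h replicate 1 and 528 without uninfected 72 h replicate 1.

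The infection effect differed between the 3 windows for 70 genes, among them the Ly49 family gene Klra16, the granzyme gene Gzma and the stefin gene Stfa3. Klra16 was at -0.37 ± 0.45 at 8 to 24 h, 1.97 ± 0.51 at 32 to 48 h and 4.55 ± 0.49 at 56 to 72 h, and Gzma at 0.19, 2.45 and 4.34. Stfa3, a cysteine protease inhibitor gene of neutrophils, was at -0.02 ± 0.34 and 0.62 ± 0.38 in the earlier windows and 3.76 ± 0.37 in the last. The 10 smallest adjusted p values belonged to Stfa3, Stfa2l1, Klra1, Stfa2, Klra16, Gzma, Klra4 and Klra22, each at 0.000539, and to Klre1 and Stfa1 at 0.000948. Which Klra or Stfa members changed is uncertain, as they can bind to one another's probes. Of the gene lists, only NK cell markers and cytotoxic granule differed between 56 to 72 h and 8 to 24 h with an estimated correlation, by 2.17 and 2.0 in the median (adjusted p = 0.0193 and 0.0322). The monocyte list at 1.92, the neutrophil list at 1.43 and the platelet list at 1.73 differed with the preset correlation and not with an estimated one (adjusted p = 0.114, 0.124 and 0.525). So did 7 further lists with medians of 0.735 to 1.47: MHC class II, ribosomal protein, immediate early and heat shock, B cell, interferon gamma-induced, eosinophil and basophil, and type I interferon-stimulated. The median was above 0 for all 21 lists. Of 27 genes higher at 8 to 24 h and 38 higher at 32 to 48 h, 18 were shared, where 0.0637 are expected of independent lists (Fisher's exact p = 1.88e-43). All 38 were also among the 1364 higher at 56 to 72 h, where 3.22 are expected (Fisher's exact p = 1.10e-41). At 8 to 24 h and 56 to 72 h 18 were shared, where 2.29 are expected. Fisher's test counts genes as independent, which they are not, so its p values do not measure the spread between arrays. Across all 16113 genes, which are not independent replicates, the differences did not run together: the correlation was -0.161 between 8 to 24 h and 32 to 48 h, 0.121 between 8 to 24 h and 56 to 72 h, and -0.0324 between 32 to 48 h and 56 to 72 h. The arrays with a narrow range of ratios were infected ones at 8 to 24 h and uninfected ones at 32 to 48 h. Without them the median difference of all genes turned from 0.096 to -0.18 at 8 to 24 h. At 32 to 48 h it turned from -0.195 to 0.16. The correlations were not computed without these arrays, so array structure may have entered them. The windows shared no arrays, although they shared the estimate of the spread. The count of 70 was 11 without arrays 195 to 199, 37 without the 4 arrays with a narrow range of ratios and 31 with array number ranges as a block. It was 119 without time terms, 382 without arrays 206, 210, 224 and 233, which had high Alb values, and 7613 with array weights. Leaving out 1 infected array gave 128 (8 h replicate 1), 44 (16 h replicate 1), 40 (24 h replicate 1), 115 (56 h), 37 and 31 (64 h replicates 1 and 2) and 36 (72 h replicate 2). Leaving out 1 uninfected array gave 45 (either at 0 h), 120 (8 h replicate 1), 38 and 44 (16 h replicates 1 and 2), 39 (either at 24 h), 46 (32 h replicate 1), 45 (48 h replicate 2), 115 (56 h), 30 and 40 (64 h replicates 1 and 2) and 33 (72 h replicate 1).

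An effect at any of the 9 time points from 8 to 72 h was called for 231 genes, and with array weights for 4557. Gzmb had the smallest adjusted p, 2.92e-07, with differences of 1.78 at 8 h, 1.78 at 16 h, 1.67 at 24 h, 4.30 at 32 h and 4.70 at 72 h. It was followed by Klra22, Ms4a6d, Klra16 and Cxcl10 at 4.07e-06 and by Gzma, Klra4, Ifit3, Serpinb9b, which encodes an inhibitor of granzyme type proteases, and Ifit1 at 5.02e-06. Ncr1 was at 1.38 at 8 h, -0.63 at 16 h, -0.57 at 24 h, 0.84 at 32 h, 1.32 at 40 h, 3.37 at 48 h, 2.53 at 56 h, 3.60 at 64 h and 4.0 at 72 h. Time points with 1 array in an arm (40, 48 and 56 h) were assumed to vary like the others, and single time points were not tested on their own. The count was 396 without either infected array at 0 h, 1097 and 1172 without infected 16 h replicate 1 or 2, 120 and 142 without infected 64 h replicate 1 or 2, and 150 without infected 72 h replicate 2. It was 125 without uninfected 64 h replicate 1 and 140 without uninfected 72 h replicate 1.

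At 0 h infected and uninfected blood differed in 3 genes, 1 higher and 2 lower, each resting on 1 array (2 and 2 arrays). At an unadjusted p below 0.05 there were 83 higher and 385 lower genes, where 804 in all are expected by chance. Olfr419, an olfactory receptor gene, was higher by 4.55 ± 0.82 (adjusted p = 0.0330) because the 1 uninfected array that measured it stood at -4.98 while the later uninfected arrays averaged 0.54, and its difference was -0.67 without time terms. Bbs1, a gene of cilia, was lower by 3.63 ± 0.57 (adjusted p = 0.0227), from 1 infected array at -3.76. Without arrays 206, 210, 224 and 233 the 0 h count was 0 higher and 72 lower, and after centring it was 0 in limma, with 572 genes at an unadjusted p below 0.05. The direction turned with the array left out: without infected 0 h replicate 1 there were 0 higher and 78 lower genes, and without infected 0 h replicate 2 there were 42 higher and 3 lower. Other arrays left out gave 0 (uninfected 0 h replicate 1) and 1 (infected 40 h or uninfected 8 h replicate 2).

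In uninfected blood 0 of 16113 genes passed the limma test of a 24 h cycle, with 3350 at an unadjusted p below 0.05, where 806 are expected by chance. The genes with the smallest p were Tspan3, Rev3l and Pigu, each at an adjusted p of 0.147. Of 18 measured genes of the circadian clock, the transcription feedback loop that keeps daily time, Arntl, the gene of its activator BMAL1, had the smallest adjusted p at 0.208 and Hlf the largest at 0.613, with Dbp at 0.237, Nr1d1 at 0.248 and Per1 at 0.250. The clock hour of 0 h is not in the labels. With array weights, which ran from 0.28 to 565 among the uninfected arrays and so let a few arrays decide, 12179 genes passed. After quantile normalization 281 passed, with centring and scaling together 211, and without uninfected 56 h or uninfected 64 h replicate 1 there were 2 and 4. Without arrays 206, 210, 224 and 233 there were 2.

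Some arrays stood apart in ways that cut across infection. Arrays 241, 242, 244 and 245 (infected 8 h and 16 h, both uninfected 32 h arrays) had standard deviations of 0.868 to 0.899 against at least 1.04 on the others. Alb, the gene of serum albumin made by hepatocytes, was at 6.20 on infected 8 h replicate 1, 4.62 on infected 32 h replicate 2, 3.58 on infected 0 h replicate 1 and 3.12 on uninfected 56 h replicate 1, against a median of -1.70 over all arrays. Rag1, a recombinase gene of developing lymphocytes, was at 6.65 on infected 0 h replicate 1 against a median of -1.57 on the others, and Cd8a at 4.84 against 0.65. The windows at 8 to 24 h, 32 to 48 h and 56 to 72 h each hold 1 of the arrays with a high Alb value.

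**Figure D3:**
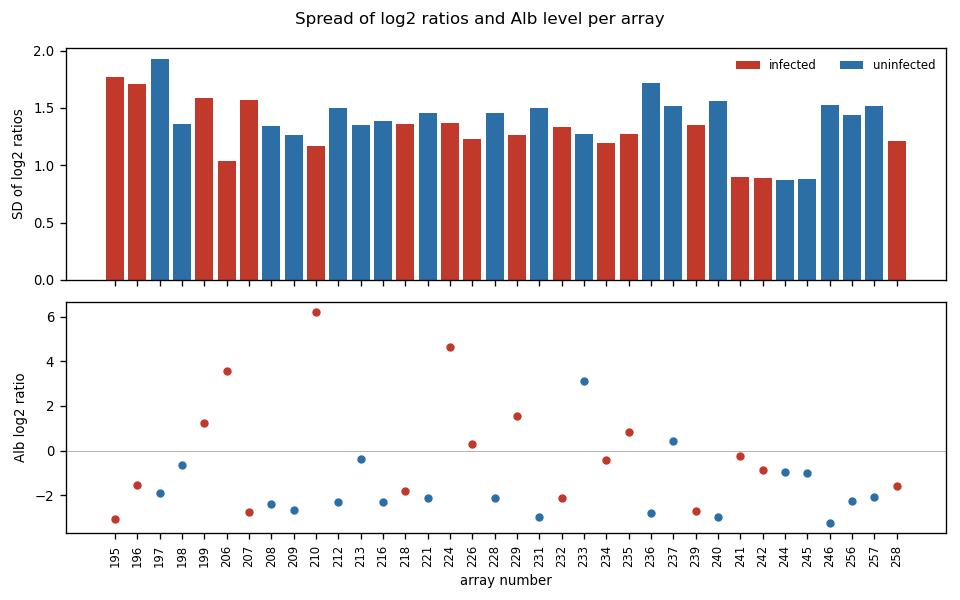
Standard deviation of the log2 ratios of each array (bars, upper panel) and Alb log2 ratio (points, lower panel) against array number, in red for infected and blue for uninfected arrays. The 4 arrays 241, 242, 244 and 245 have the lowest standard deviations, 0.868 to 0.899, and Alb is above 3 on 4 arrays, with a maximum of 6.20.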

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

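The tests of the narrow range of ratios, the test of Alb against infection and the choice of the 4 arrays with high Alb values were made only after the results were seen, and the other tests named here were fixed earlier. The reading of the test of mixed reference signal was also changed to undecided after its values were seen, because its measures pointed opposite ways. A single scale factor is likewise read as undecided, against the rule set for its test.

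The infection effect differed between the 3 windows for the genes named here. The adjusted p of this test was 0.000539 for Stfa3, Stfa2l1, Klra1, Stfa2, Klra16, Gzma, Klra4 and Klra22 and 0.000948 for Klre1 and Stfa1. The NK cell marker list was higher by 2.17 and the cytotoxic granule list by 2 in the infection effect at 56 to 72 h than at 8 to 24 h, in a test of the difference itself. Probes without a single gene symbol, which the comparisons of genes do not use, also differed between infected and uninfected blood: 95 of 5757 at 8 to 72 h, all higher, and 235 at 56 to 72 h, of which 233 were higher and 2 lower.

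In 4 groups of arrays 1 list score stood far from the others, where 126 groups were examined and 6.3 are expected by chance. Infected 16 h replicate 2 had the highest interferon gamma-induced score, 1.89 against 1.01 for the nearest infected array of its window, and the highest type I interferon-stimulated score, 2.15 against 1.13. The T cell score of uninfected 8 h replicate 1 was -0.714, against 0.0991 for the nearest. The immediate early and heat shock score of infected 48 h replicate 1 was 0.871, against 0.134 for the nearest.

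Arrays 241, 242, 244 and 245, which are 2 infected arrays (8 h and 16 h) and both uninfected arrays at 32 h, had the narrowest ranges of ratios, with standard deviations of 0.868 to 0.899. Infection status as the source was argued against over the 19239 probes measured on all arrays, a smaller set than that of the correlations given above. There the infected of these arrays correlated at a mean of 0.919 with the uninfected ones and at most at 0.796 with any other infected array. A single scale factor for every probe failed the range of slope ratios set for it on each of these arrays, but is left undecided here. The slope of the ratios below 0 was on average 0.615 of the slope above 0, where 1 factor gives equal slopes. The tails, shortened alike, went with 1 factor, and slopes of the other arrays were not computed for comparison. Reference RNA or signal mixed into the blood channel may have narrowed them, and the values do not decide it, since the tails were shortened alike (ratio of the shares kept 1.03) while the slopes, at 0.575 to 0.644, were not. These arrays have neighbouring numbers, and no label gives a day or batch.

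Alb and Apoa1, a pair of genes of plasma proteins made by the liver, were high on a few arrays, with Alb at 6.20, 4.62 and 3.58 on infected 8 h replicate 1, infected 32 h replicate 2 and infected 0 h replicate 1. RNA of hepatocytes in these samples is a candidate source: the other genes of a 27-gene hepatocyte list, 0 of them in a blood cell list, lay on each of the 3 at least 5.81 SD above the infected arrays without a high Alb value. Lists of pancreas, fat, heart muscle, lung, skeletal muscle and skin genes argued against RNA of these organs, as none exceeded 3 SD on any of these arrays (0 of 3), but the thymocyte list lay 9.81 SD above on infected 0 h replicate 1. Infection itself was not excluded, with Alb at 0.07 ± 2.69 (SD, n = 17) in infected and -1.66 ± 1.52 (SD, n = 19) in uninfected blood (permutation p = 0.0192), although 1 of these arrays is from 0 h and uninfected 56 h replicate 1 had the next highest Alb, 3.12.

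T cell genes were high on infected 0 h replicate 1, one of the arrays with a high Alb value. Thymocyte RNA in that sample may account for this: Rag1, Rag2, Dntt, Ptcra and Arpp21, genes of developing lymphocytes, were each highest on this array among the arrays that measured them (20 for Rag2 and 36 for the others). The mean of those measured lay 5.38 SD above the other 35 arrays. A larger share of blood T cells, whose list lay 4.73 SD above, was argued against as the whole source, because blood T cells lack the recombinase Rag1, at 6.65 here against a median of -1.57. Bone marrow cells stayed open, with their list of 14 genes at 2.32 SD. Of the 17 thymocyte genes measured 4 are also in a blood cell list, and no sort or gate was named in the labels.

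Splits of the arrays within each hour asked whether a random grouping gives as many genes, the real split included. For 32 to 48 h, 1 of 54 splits reached 38 genes (highest other 16), and for 56 to 72 h, 1 of 36 reached 1373 (highest other 143). No other split reached the real count, but these are the smallest shares that 54 and 36 splits allow. They lie under 0.05, not adjusted over the split tests. Both uninfected arrays at 32 h had a narrow range of ratios, so the real split also follows array structure there. Without the 4 arrays of that kind 10 genes passed at 32 to 48 h. For 8 to 72 h, 2 of 100 reached 261 (highest other 2570), for the difference between windows 3 of 100 reached 70 (highest other 623), and for any time point 2 of 100 reached 231 (highest other 2429). For 8 to 24 h, 4 of 100 splits reached 27 genes, and the 3 others, with 421, 2735 and 230, each placed all 3 arrays of numbers 195 to 199 of that window in 1 arm. These 3 splits follow the array numbers. In these 4 results the shares lie under 0.05 unadjusted, but other splits called several times more genes than the real one, so they give little ground to exclude chance. Splits above the real count placed 4 of the 5 arrays 195 to 199 in the first arm for 8 to 72 h. For the difference between windows they placed 2 or 3 of the 5 there, and for any time point 3 of 5. A complete split along these numbers was thus seen only at 8 to 24 h. With the number ranges as a block 32 genes passed at 8 to 24 h. For the cycle the real count was 0 in limma, with 3350 genes at an unadjusted p below 0.05, which all 100 splits reach by definition (highest other 72), so the splits decide nothing there.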

How the results depend on the processing

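The results without sets of arrays (241, 242, 244 and 245; 195 to 199; 206, 210, 224 and 233) and with centring and scaling combined were chosen only after the data had been seen. No paired analysis was possible because the replicate numbers follow the order of deposition and pair no arrays. Signal over background was not analysed here, so the effect of weak signals is unknown.

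Whether lists kept their direction and their side of the threshold differed between lists and tests. The type I interferon-stimulated list kept both in 53 of 53 at 8 to 24 h, 52 of 53 at 32 to 48 h (not in the exact permutation test) and 53 of 53 at 56 to 72 h, and the cytotoxic granule list in 53 of 53 at 32 to 48 h and at 56 to 72 h but 41 of 53 at 8 to 24 h. In a count that leaves out the NK cell list, 25 of 80 list results differed in their call with the correlation estimated. With fry, another list test, 30 of the same 80 differed in call or direction. Of 126 named gene results, 118 kept theirs after centring, 99 after scaling, 118 after quantile normalization, 123 with robust moderation and 108 without arrays 195 to 199. With the correlation estimated 16 of 84 list tests passed, against 42 with the preset one, and the NK cell list over 8 to 72 h, at a median of 0.845, had an adjusted p of 0.0518. With fry 26 passed and the erythroid direction over 8 to 72 h (median -0.0196) was reversed. Exact permutation tests, run for the 3 windows alone, gave 16 where the preset correlation gave 30. Calls lost with the correlation estimated include the NK cell, platelet and neutrophil lists over 8 to 72 h, cytotoxic granule at 8 to 24 h and interferon gamma-induced at 56 to 72 h.

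Counts moved more than lists did. Unless stated, the cause was not tested. After centring, 84 genes passed at 32 to 48 h, 843 at 56 to 72 h and 0 at 0 h. After scaling, 0 passed at 8 to 24 h (790 at an unadjusted p below 0.05 in limma), 18 at 32 to 48 h and 5 at 0 h, and the erythroid median turned to 0.156 at 8 to 24 h and was -0.401 at 32 to 48 h. After quantile normalization, 62 passed at 32 to 48 h, 727 at 56 to 72 h, 0 at 0 h and 281 for the cycle, and the median of the list erythroid, 8 to 24 h, was -0.00423. With centring and scaling, 0 passed at 8 to 24 h (1310 unadjusted), 648 at 56 to 72 h, 7 at 0 h and 211 for the cycle, and list medians were -0.254 for MHC class II over 8 to 72 h, -0.00869 for the list B cell, 8 to 24 h, -0.0979 for NK cell markers at 8 to 24 h and -0.234 for erythroid at 32 to 48 h.

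With genes measured on all 36 arrays, and with single probes, 0 passed at 0 h. Array weights, which ran from 0.0922 to 565 and so let a few arrays decide, gave 985 over 8 to 72 h, 3287 at 32 to 48 h (264 higher and 3023 lower, so that most calls of that window were lower), 5042 at 56 to 72 h (4652 higher and 390 lower), 0 at 0 h, 7613 for the difference between windows, 4557 for any time point and 12179 for the cycle, and a ribosomal median of 0.451 at 8 to 24 h. With ranges of array numbers as a block there were 431 over 8 to 72 h, 760 at 56 to 72 h and 31 for the difference. With the array number as a linear term there were 479 over 8 to 72 h, and at 32 to 48 h the medians turned to 0.374 for glycolysis, 0.304 for heme and oxidative stress, 0.401 for immediate early and heat shock, 0.273 for proliferation and 0.0657 for the list ribosomal protein, 32 to 48 h. Without time terms there were 44 at 8 to 24 h, 106 at 32 to 48 h, 668 at 56 to 72 h, 27 at 0 h and 119 for the difference, and Olfr419 at 0 h turned to -0.669. Fitted on the arrays of a window alone, which leaves fewer arrays for the spread, 0 passed at 0 h, 13 at 8 to 24 h, 25 at 32 to 48 h and 2884 at 56 to 72 h.

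Without arrays 241, 242, 244 and 245 there were 10 at 32 to 48 h and 37 for the difference. List medians were then -0.0339 for NK cell markers and -0.604 for proliferation at 8 to 24 h, and at 32 to 48 h -0.13 for erythroid, 0.448 for glycolysis, 0.472 for immediate early and heat shock, 0.540 for proliferation and 0.218 for ribosomal protein. The median difference of all genes was then -0.184 at 8 to 24 h and 0.1645 at 32 to 48 h. Without arrays 195 to 199 there were 6 at 8 to 24 h, 25 at 32 to 48 h, 862 at 56 to 72 h and 11 for the difference, and the ribosomal median at 8 to 24 h was 0.709. Without arrays 206, 210, 224 and 233 there were 3242 at 56 to 72 h, 72 at 0 h, 382 for the difference and 2 for the cycle, and the NK cell median at 8 to 24 h was -0.277.

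Leaving out 1 array at a time gave 191 to 343 genes over 8 to 72 h, 19 to 34 at 8 to 24 h, 12 to 44 at 32 to 48 h, 441 to 2541 at 56 to 72 h, 0 to 78 at 0 h, 30 to 128 for the difference, 120 to 1172 for any time point and 0 to 4 for the cycle, and 36 to 45 list tests. The NK cell median at 8 to 24 h ran from -0.277 (without infected 8 h replicate 1) to 0.0267 (without uninfected 24 h replicate 1). The erythroid median at 32 to 48 h ran from -0.186 to 0.154. Where an array was the last of its arm at an hour, that hour gave no difference. Of 4533 named gene results, 4346 kept their call and 187 lost it.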

Other observations

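The gene lists in this part and the choice of the genes named were made only after the values were seen, so their counts are descriptions and not tests.

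Genes of MHC class I presentation, the molecules that display peptides to CD8 T cells and that NK cells monitor, were higher at 56 to 72 h, with 11 of 17 past the limma threshold and a median of 1.63, or 1.20 relative to all genes. B2m, the light chain of MHC class I, rose by 2.96 ± 0.50 (adjusted p = 0.000239), H2-K1, a heavy chain, by 3.13 ± 0.51 and Psmb9, an immunoproteasome subunit, by 2.45 ± 0.41, each with all 5 infected arrays above all uninfected arrays. At 8 to 24 h B2m was at -0.09 ± 0.46, and the median of the list was 0.22. Of innate sensor and inflammasome genes 11 of 22 rose at 56 to 72 h, with a median of 1.37, among them Tlr7, a receptor for single-stranded RNA, by 3.30 ± 0.51 and Casp1, the protease that processes interleukin 1 beta, by 3.06 ± 0.43. Complement and pentraxin genes had 5 of 14 higher, with a median of 0.63, or 0.20 relative to all genes, among them C1qb at 2.52 ± 0.61 and Cfb at 3.87. After centring, Cfp, C1qc and C3ar1 of the complement genes did not pass (adjusted p = 0.0631, 0.126 and 0.0905), nor did Erap1 and Psmb8 of MHC class I presentation and Pycard and Tlr2 of the sensors.

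A pair of liver genes stood among the 27 higher at 8 to 24 h. Ugt2b34, a glucuronosyltransferase, rose by 2.29 ± 0.40 (adjusted p = 0.00377) and Hao1, a peroxisomal oxidase, by 2.11 ± 0.41 (adjusted p = 0.0134), with all 6 infected arrays above all uninfected arrays of that window. For Ugt2b34 the uninfected arrays of the window ran from -3.81 to -1.60, and those of other hours from -2.42 to -0.77. The infected arrays of the window ran from -1.31 to 1.35. Part of its difference thus lay in low uninfected values of this window. For Hao1 the closest were infected 24 h replicate 2 at -2.94 and uninfected 8 h replicate 1 at -2.95. Hao1 was also high on the arrays with a narrow range of ratios in both arms, at -0.28 and -0.49 on the infected and -0.59 and -0.71 on the uninfected ones. Ugt2b34 was at -0.48 and -0.90 on these infected arrays and at -0.95 and -1.09 on the uninfected ones. Without the 4 arrays with high Alb values the differences of Ugt2b34 and Hao1 were 1.96 and 2.05, with adjusted p values of 0.0316 and 0.0733. At 56 to 72 h the differences were -0.62 and -0.26 with all arrays.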
